A study of Caenorhabditis elegans with 12 samples.

How the data were processed

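Polyadenylated RNA was sequenced from whole C. elegans at adult day 1, grown at 20 °C on E. coli OP50; the animals had been picked at the L4 stage, the last larval stage, per the labels' protocols. The 4 strains compared were N2, the laboratory wild type; AV477, a dsb-2(me96) mutant; AV157, a spo-11(me44) mutant; and TY4986, an htp-3(y428) mutant. Each strain had 3 libraries, which the series text calls biological replicates, and a library is named here by its mutated gene and replicate number. The genome build was WBcel235, per the submitters' processing notes. The aligner, the counting method, the annotation release and the strandedness of the counting are not given in the sources used here.

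Each deposited table lists 20222 genes with RPKM values (reads scaled by exon length and mapped reads) and TPM values (reads scaled by exon length to a fixed total per library), per the file headers. The authors' RPKM column and a column headed expression value were identical in every row. The TPM values the authors deposited sum to the same total in each library, as the unit requires. Of the 20222 gene identifiers, 20052 (99.2%) were found in the WBcel235 annotation used here, and 5470 had the same start and end there, so positions are given as the authors' tables give them, counted from 1.

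The tables hold no counts. Low RPKM values were whole multiples of the worth of 1 read, which gave each library's depth. It ranged from 32422219 to 42527086 mapped reads. With these depths, 18041 of 18042 genes with a value in at least 4 libraries came out as whole reads within 0.05 reads in every library. The listed genes held between 78.8% of the mapped reads (dsb-2 replicate 1) and 97.9% (dsb-2 replicate 3). At this depth 1 read on a gene with 1 kilobase of exon was worth 0.0293 to 0.0437 TPM.

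The test had been planned for counts, with a fallback for other units that was fixed before the data were examined. The fallback was used: limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(TPM + 1). Genes with at least 1 TPM in at least 3 libraries were kept, 13650 in all. All 12 libraries entered one fit with a mean per strain. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. The fallback named no column. TPM was taken over RPKM before any calls were seen, because RPKM divides by mapped reads that include those outside the listed genes. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low values.

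The 30 fixed gene lists were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over lists and over the 3 mutant comparisons with N2. The same test with an estimated correlation, and limma's fry, were run beside it. Chromosomes were compared by Fisher's exact test among genes tested. The genes named were fixed by rule: the 3 mutated genes; the 10 highest and 10 lowest called genes whose 3 mutant libraries all lay on one side of the 3 N2 libraries, with a mean of at least 5 TPM in the higher group; and the 3 members of each list with the smallest p. Between mutants the rule took the 5 highest and 5 lowest. The minimum had been written for CPM and was applied to TPM.

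Alternatives were median-of-ratios scaling, upper-quartile scaling, no filter, a minimum of 5 TPM, only the strains compared, the replicate number as a block, each library left out in turn, a fold change of at least 2, and pseudocounts of 0.1 and 5. RPKM in place of TPM and limma-voom on the rebuilt reads were added after the data were seen. Deviations from the strain means were correlated between same-numbered libraries: every pair of spo-11 and htp-3 exceeded 0.1, with r between 0.12 and 0.44 across genes, so those numbers were treated as pairing for that comparison, from the data and not from the labels. The counts given for it come from the planned fit without the block, since the block moved them by less than 1.5 times (1189 higher and 5391 lower). This pairing is uncertain, because values of similar size and either sign were seen elsewhere. Between dsb-2 and htp-3 they were 0.36, -0.14 and -0.39.

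The procedure was tested on simulated data for the dsb-2 comparison with 13650 genes. Over 3 simulated sets with 200 changed genes each, 75.0% of genes changed by 1 on the log2 scale and 99.3% of those changed by 2 were recovered. In these sets 28 unchanged genes were called. The changed genes were drawn only from those of higher value in N2, so recovery at low values was not measured. The simulated noise was independent between genes, unlike that of real libraries. Libraries of one strain differed beyond sampling noise in the rebuilt reads in every pair, with a chi-square per degree of freedom of at least 52.4, so none was counted as a repeat. Reads shared by near-identical genes, overlapping genes or antisense genes could not be told apart, and the msp, histone, collagen and ribosomal protein genes are uncertain as single genes for that reason. Figures were drawn with matplotlib 3.10.9.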

Results

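The transcriptomes of whole adults of N2 and of 3 meiotic mutants were measured at day 1 of adulthood, with 3 libraries per strain. Each mutation was present in a single strain. In every comparison with N2, an effect of the mutation therefore cannot be told apart from other differences of that strain. The mutated genes act in meiotic recombination: spo-11 encodes the enzyme that makes meiotic double-strand breaks, dsb-2 promotes their formation, and htp-3 encodes a chromosome axis protein. Mapped reads ranged from 37621656 to 42378902 in N2, 32422219 to 42527086 in dsb-2, 34938360 to 35494475 in spo-11 and 36250956 to 38473833 in htp-3. Of 20222 genes, 3860 to 4511 were listed at 0 in N2 libraries and 4075 to 4542 in dsb-2 libraries. The same number was 1493 to 2081 in spo-11 and 2746 to 3130 in htp-3. The first principal component held 79.6% of the variance and the second 10.5%.

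**Figure D1:**
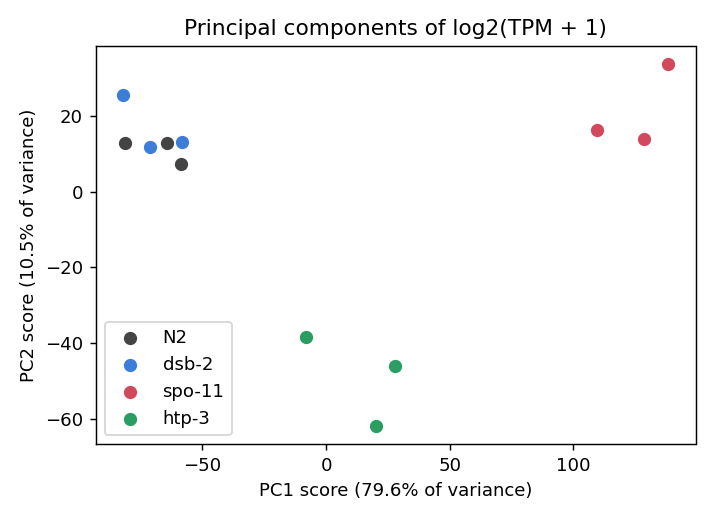
Principal component scores of the 12 libraries from log2(TPM + 1) of the genes tested, one point per library. On the first component the spo-11 libraries lie between 109 and 138, the htp-3 libraries between -8.01 and 27.7, and the N2 and dsb-2 libraries between -82.1 and -58.3.

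The mutated genes were examined first, since they bear on the labels. The dsb-2 transcript (chromosome II, 14411095 to 14412218, WBcel235) was at 18.5 ± 1.43 TPM in dsb-2 against 58.5 ± 3.64 TPM in N2 (SD, n = 3 each), a log2 fold change of -1.61 ± 0.21 (SE; limma adjusted p = 0.00149). The htp-3 transcript (chromosome I, 4827072 to 4829794) was at 9.50 ± 2.82 TPM in htp-3 against 71.6 ± 5.42 TPM in N2 (SD, n = 3 each), a log2 fold change of -2.82 ± 0.21 (SE; limma adjusted p = 4.69e-07). The spo-11 transcript (chromosome IV, 11123133 to 11124862) was at 36.2 ± 2.18 TPM in spo-11 and 33.3 ± 11.2 TPM in N2, a log2 fold change of 0.16 ± 0.26 (SE; limma adjusted p = 0.569). Under median-of-ratios scaling that value was -0.65, with an adjusted p of 0.00685. The dsb-2 transcript was also lower in spo-11 (-0.53, adjusted p = 0.0320) and htp-3 (-0.87, adjusted p = 0.00305), and the htp-3 transcript in spo-11 (-1.18, adjusted p = 9.53e-05), so a fall of either alone does not identify the strain. A point mutation need not lower its transcript, so the spo-11 label is not checked by this gene.

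**Figure D2:**
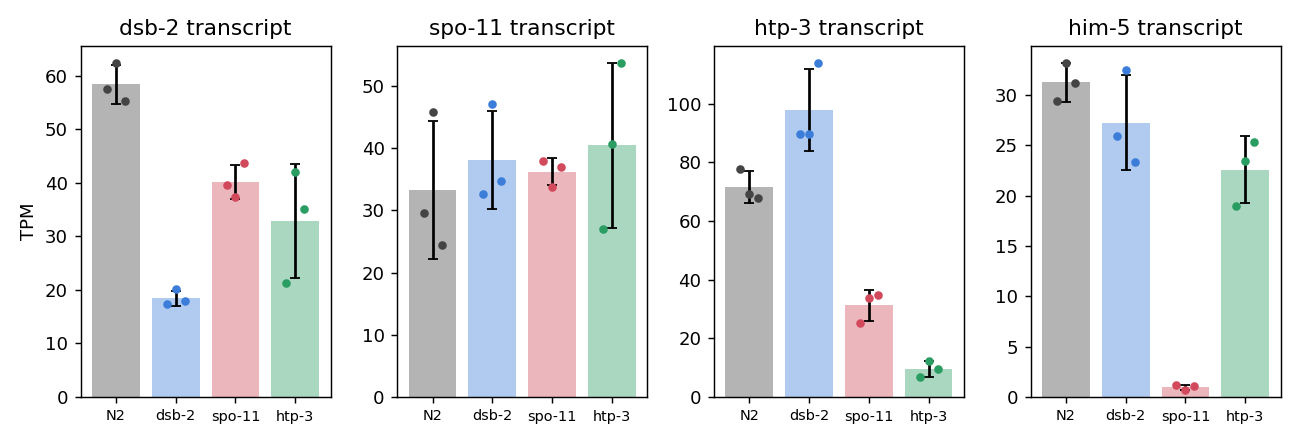
TPM of the 3 mutated genes and of him-5 in each strain; points are libraries, bars are means and whiskers are SD (n = 3). The dsb-2 and htp-3 transcripts are lowest in their own mutants, the spo-11 transcript overlaps between strains, and him-5 is near 1 TPM in the spo-11 libraries.

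The dsb-2 comparison asks how the whole-animal transcriptome of a strain mutated in a break-promoting factor differs from that of N2. Few genes changed: 26 were higher and 10 lower than in N2 of 13650 tested. Of the higher genes, 22 lay on chromosome V, 16 of them between 2348215 and 2531174. They included the C-type lectin gene clec-209, at 595 ± 204 TPM in dsb-2 against 87.8 ± 33.5 TPM in N2 (SD, n = 3 each), a log2 fold change of 2.75 ± 0.30 (SE; adjusted p = 0.000272). F56A4.3 rose by 4.56 ± 0.34, W09B7.2 by 2.38 ± 0.25 and the F-box gene fbxa-192 by 2.04 ± 0.24 (log2, SE). Several of these genes have a near-parallel partner, such as clec-209 and F56A4.2, and such genes are uncertain as single genes. In the cluster such pairs run from clec-209 and F56A4.2 to C13B7.6 and Y45G12C.16. One member of each pair starts between 2351676 and 2421867, and its partner, in the same order, between 2459637 and 2530146. The 16 genes are therefore not 16 separate findings.

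Among the 10 lower genes were dsb-2 itself and 3 cuticle collagen genes on chromosome II: col-17 (log2 fold change -2.21 ± 0.39), sqt-1 (-1.66 ± 0.29) and rol-8 (-1.63 ± 0.29). The calls of all 3 collagen genes ended without N2 replicate 2, N2 replicate 3, dsb-2 replicate 1 or dsb-2 replicate 2, and that of rol-8 also without dsb-2 replicate 3. The col-17 call also ended with limma-voom on rebuilt reads (-3.91, adjusted p = 0.0661), and its adjusted p ranged from 0.00142 to 0.145 over the alternatives. The cuticle collagens as a list had 3 of 126 tested members lower and none higher, or 8 lower when adjusted over the list alone and 6 lower under median-of-ratios scaling. Their median log2 fold change was -0.25, with a camera adjusted p of 2.96e-12 and an adjusted p of 0.731 with an estimated correlation. The oocyte and eggshell list had a median of 0.37 with 0 of 30 members called, and the germline stem cell and P granule list a median of 0.36 with 0 of 22 called. Their camera adjusted p-values were 1.27e-06 and 7.71e-05, and each was 0.731 with an estimated correlation. Both rested in part on dsb-2 replicate 3: its mean change was 0.61 for the oocyte list, against 0.27 and 0.15 in the other dsb-2 libraries, and 0.65 for the germline list, against 0.02 and 0.36. Without it the medians were 0.24 and 0.23 (camera adjusted p = 0.00308 and 0.0496). The 6 vitellogenins (yolk protein precursors) had a median of 0.51 with none called over all genes and 3 higher when adjusted over the list alone (camera adjusted p = 0.00125; adjusted p = 0.731 with an estimated correlation). Camera also called the ribosomal proteins (median -0.10, adjusted p = 4.53e-06), muscle markers (0.19, 0.00332), the DNA damage response (0.15, 0.0135) and the endoplasmic reticulum response (0.20, 0.0142), with 0 members called in each. These 4 calls were each lost without at least 1 library: N2 replicate 3 or dsb-2 replicate 2 for ribosomal proteins, N2 replicate 1 for muscle, N2 replicate 3 or dsb-2 replicate 3 for the DNA damage response and N2 replicate 3 for the endoplasmic reticulum response. Of the 8 lists called, 0 kept an adjusted p under 0.05 with an estimated correlation and 0 were called by fry, and the other 22 lists were not called by camera. At an unadjusted p under 0.05 limma gave 1448 of 13650 genes in this comparison, above the share of 0.05 expected with no differences. Whether the excess comes from smaller changes or from genes that vary together was not tested. The count of lower genes rested on single libraries: it was 2 without N2 replicate 2, 3 without N2 replicate 3, 2 without dsb-2 replicate 1, 3 without dsb-2 replicate 2 and 6 without dsb-2 replicate 3. It was also 17 with the replicate number as a block.

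The spo-11 comparison asks how the strain labelled spo-11, mutated in the gene of the break-making enzyme, differs from N2. It gave 7584 higher and 3010 lower genes. The median log2 fold change of all genes tested was 0.80, so list medians are to be read against that value. Higher calls made up 71.6% of all calls; under median-of-ratios scaling there were 6033 higher and 5449 lower genes (52.5% higher) and the all-gene median was 0.16.

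The sperm lists had the highest medians of the 30 lists in spo-11. Of 28 major sperm protein genes tested, 27 were higher and none lower, with a median log2 fold change of 4.98 (camera adjusted p = 0.000161; adjusted p = 0.863 with an estimated correlation). Of 34 other sperm genes 32 were higher, with a median of 3.11 (camera adjusted p = 3.15e-05; adjusted p = 0.731 with an estimated correlation). They included spe-11 (5.34 ± 0.32) and spe-26 (3.64 ± 0.23), both log2 fold changes with SE. Innate immune effectors were higher for 44 of 48 members and lower for 1, with a median of 2.82 (camera adjusted p = 5.23e-06; adjusted p = 0.731 with an estimated correlation). The lysozyme gene ilys-3 was at 97.0 ± 30.5 TPM in spo-11 against 0.0216 ± 0.0375 TPM in N2 (SD, n = 3 each), and the infection response gene irg-5 at 222 ± 81.3 TPM against 2.19 ± 0.540 TPM. The intracellular pathogen response list had 15 of 17 members higher, with a median of 1.91 (camera adjusted p = 0.00733; adjusted p = 0.731 with an estimated correlation), including pals-32 (4.04 ± 0.21).

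Neuron and muscle markers and collagens also rose in spo-11. All 25 neuron markers were higher (median 2.17), among them sbt-1, a chaperone of neuropeptide processing (3.21 ± 0.21). Of 22 muscle markers 21 were higher (median 1.89), including the myosin gene unc-54 (3.20 ± 0.25). Camera adjusted p-values were 7.71e-05 for neurons and 0.000977 for muscle, and each was 0.731 with an estimated correlation. The cuticle collagens had 109 of 126 members higher and 1 lower (median 2.04; camera adjusted p = 2.11e-05; adjusted p = 0.731 with an estimated correlation). The intestine list had 10 of 19 members higher (median 0.99; camera adjusted p = 0.192), the hypodermis list 9 of 12 with 1 lower (median 1.35; camera adjusted p = 0.5002) and the gonad sheath list 10 of 13 with 1 lower (camera adjusted p = 0.267). None of these 3 lists was called by camera. Xenobiotic metabolism genes (69 of 101 higher, 8 lower, median 1.30) and F-box genes (129 of 181 higher, 22 lower, median 1.19) had camera adjusted p-values of 0.0313 and 0.0200, and each was 0.875 with an estimated correlation. The xenobiotic call was lost without N2 replicate 3 or spo-11 replicate 2. Genes on the X chromosome, which is largely silent in the germline, were higher for 1501 of 1861 and lower for 68, with a median of 1.21 (camera adjusted p = 1.73e-07; adjusted p = 0.731 with an estimated correlation).

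Oocyte and germline genes fell in spo-11. Of 30 oocyte and eggshell genes 26 were lower and 3 higher, with a median of -1.20 (camera adjusted p = 7.21e-10). The egg-5 gene changed by -1.76 ± 0.21 and cpg-3 by -1.63 ± 0.18, while perm-4 rose by 1.02 ± 0.13, a call that ended under median-of-ratios scaling (0.18). The germline stem cell and P granule list had 13 of 22 members lower (median -0.82), the meiotic list 35 of 49 lower and 1 higher (median -0.77), and the DNA damage response list 18 of 29 lower and 1 higher (median -0.68). Their camera adjusted p-values were 2.71e-06, 1.33e-11 and 1.84e-07. Proteasome subunits were lower for 30 of 32 (median -0.86, camera adjusted p = 1.37e-13) and ribosomal proteins for 72 of 81, with 3 higher (median -0.57, camera adjusted p = 3.89e-18). With an estimated correlation the adjusted p was 0.731 for each of these 6 lists.

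Single genes fell further. The him-5 transcript, from a gene needed for crossovers on the X chromosome, was at 0.964 ± 0.261 TPM in spo-11 against 31.3 ± 1.91 TPM in N2 (SD, n = 3 each; log2 fold change -4.05 ± 0.20, limma adjusted p = 1.29e-09). The transcription factor gene lsy-27 was listed at 0 in all 3 spo-11 libraries and at 16.9, 15.7 and 15.8 TPM in the N2 libraries. The gene fbxb-7 was listed at 0 in all 3 against 14.01, 11.1 and 7.39 TPM. For him-5, lsy-27 and fbxb-7 an effect of spo-11 could not be told apart from a further lesion in the strain. The same doubt, and that of a wrong label, covers every call and list of the spo-11 comparison, since the spo-11 transcript does not check the label. The desaturase gene fat-7 changed by -3.59 ± 0.25. Of 6 vitellogenins 3 were lower, namely vit-1 (-3.09 ± 0.29), vit-4 (-2.88 ± 0.29) and vit-3 (-2.59 ± 0.27), and 1 was higher (list median -1.26; camera adjusted p = 0.0341; adjusted p = 0.739 with an estimated correlation). The list call was lost without N2 replicate 3.

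The remaining lists moved in both directions or followed the all-gene median in spo-11. Lipid metabolism genes were higher for 29 of 45 and lower for 5, DAF-16 targets for 15 of 20 and 2 (median 1.07), and early embryo markers for 16 of 20 and 2 (median 1.21). Heat shock genes were higher for 13 of 22 and lower for 4, with a median of 1.79 although camera placed the list's direction below the other genes (adjusted p = 0.718). Medians changed sign under median-of-ratios scaling for oxidative stress genes (0.53 to -0.17; 15 of 27 higher, 2 lower), histones (0.49 to -0.18; 27 of 60 higher, 10 lower), the endoplasmic reticulum response (0.14 to -0.70; 8 of 21 higher, 4 lower) and the mitochondrial response (0.05 to -0.74; 4 of 15 higher, 3 lower). Respiratory chain genes were higher for 8 of 36 and lower for 6 (median -0.00), but for 1 and 29 under median-of-ratios scaling (median -0.84). Under the same scaling the higher and lower counts were 20 and 16 for lipid metabolism, 8 and 4 for DAF-16 targets, 10 and 10 for oxidative stress genes, 17 and 20 for histones, 3 and 13 for the endoplasmic reticulum response and 2 and 11 for the mitochondrial response. They were 12 and 9 for heat shock genes, 60 and 22 for xenobiotic metabolism, 108 and 47 for F-box genes, 86 and 5 for collagens, 0 and 21 for germline stem cell genes and 1083 and 262 for X chromosome genes. Intestine had 8 and 6, hypodermis 7 and 3, gonad sheath 8 and 3, and early embryo markers 14 and 4. Only 4 of 21 listed markers of male soma passed the filter, and 3 of those were higher, including her-1 (1.65 ± 0.17). Adjusted over the list alone, the counts in spo-11 were 1 higher and 17 lower for the DNA damage response, 5 and 4 for the endoplasmic reticulum response, 110 and 1 for collagens, 26 and 9 for histones, 7 and 4 for the respiratory chain and 1505 and 69 for X chromosome genes, and those of the other lists did not change.

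**Figure D3:**
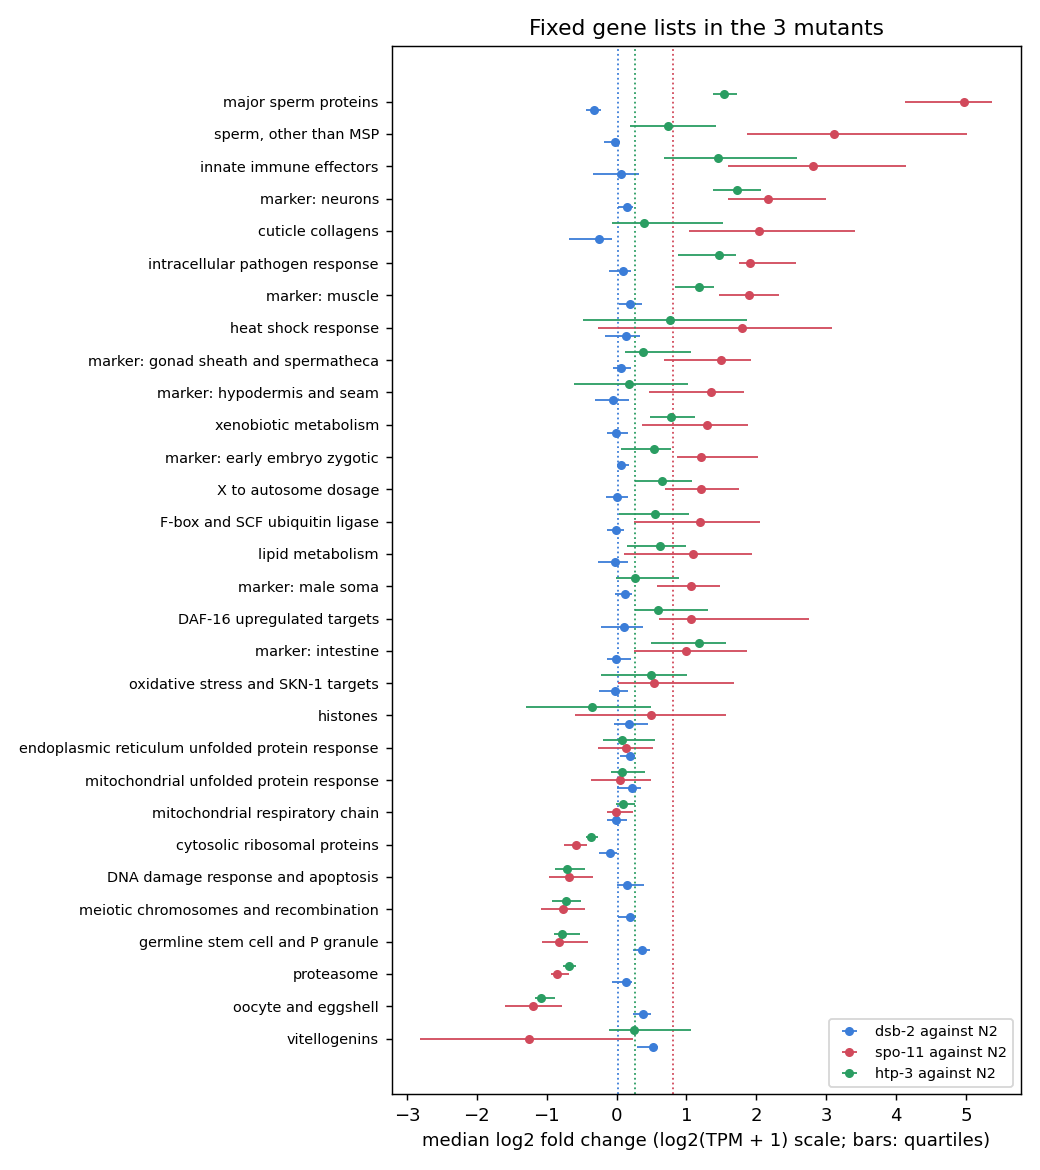
Median log2 fold change on the log2(TPM + 1) scale of the members of each fixed list in each mutant against N2, with bars from the lower to the upper quartile; dotted lines mark the median of all genes tested (0.02 in dsb-2, 0.80 in spo-11 and 0.27 in htp-3). Major sperm proteins have the highest median in spo-11. Under median-of-ratios scaling the medians of several lists near 0 change sign, such as histones in spo-11.

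The htp-3 comparison asks how a strain mutated in a chromosome axis protein differs from N2. It gave 5397 higher and 2684 lower genes, with an all-gene median of 0.27. Higher calls made up 66.8% of all calls, and 47.0% under median-of-ratios scaling (4213 higher, 4743 lower). The count of lower genes was 1789 without htp-3 replicate 1.

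Immune, intestine, muscle and neuron genes rose in htp-3. Innate immune effectors were higher for 37 of 48 and lower for 0 (median 1.45, camera adjusted p = 6.60e-08), with dct-17 at 65.7 ± 10.7 TPM against 0.994 ± 0.434 TPM in N2 (SD, n = 3 each). The gene dod-21, named for lying downstream of daf-16, was at 64.0 ± 15.96 TPM against 0.201 ± 0.115 TPM, and the insulin-like peptide gene ins-7 at 56.0 ± 36.0 TPM against 1.32 ± 0.363 TPM. The intracellular pathogen response had 14 of 17 members higher (median 1.47, camera adjusted p = 6.07e-05), including skr-5 (3.31 ± 0.31). Intestine markers were higher for 14 of 19 (median 1.18, camera adjusted p = 0.000341), muscle markers for 20 of 22 (median 1.18, camera adjusted p = 3.16e-05) and neuron markers for 23 of 25 (median 1.72, camera adjusted p = 1.73e-07). X chromosome genes were higher for 1174 of 1861 and lower for 72 (median 0.65, camera adjusted p = 8.10e-09). Each of these 6 lists had an adjusted p of 0.731 with an estimated correlation.

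Metabolic genes and sperm genes rose in part. Xenobiotic metabolism genes were higher for 72 of 101 and lower for 7 (median 0.79, camera adjusted p = 9.27e-05; adjusted p = 0.731 with an estimated correlation), including cyp-13A5 (4.16 ± 0.37). Lipid metabolism genes were higher for 24 of 45 and lower for 2 (median 0.62, camera adjusted p = 0.0313; adjusted p = 0.731 with an estimated correlation), including cpt-4, a carnitine palmitoyl transferase gene (3.01 ± 0.24), a list call lost without htp-3 replicate 1. F-box genes were higher for 107 of 181 and lower for 21 (median 0.55, camera adjusted p = 0.00373; adjusted p = 0.875 with an estimated correlation). Major sperm protein genes were higher for 23 of 28 and lower for 1 (median 1.54, camera adjusted p = 0.0229; adjusted p = 0.903 with an estimated correlation), but fry did not call the list (adjusted p = 0.107) and only 11 were higher under median-of-ratios scaling. Camera's call was lost without N2 replicate 1, N2 replicate 2, htp-3 replicate 1 or htp-3 replicate 3 (adjusted p of 0.112, 0.121, 0.109 and 0.0760). Other sperm genes were higher for 14 of 34 and lower for 2 (median 0.74, camera adjusted p = 0.252). Collagens were higher for 51 of 126 and lower for 8 (median 0.39, camera adjusted p = 0.108), with col-19 at 2.12 ± 0.18.

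Oocyte, germline and proteasome genes fell in htp-3. Oocyte and eggshell genes were lower for 26 of 30 (median -1.08), germline stem cell and P granule genes for 16 of 22 (median -0.78), meiotic genes for 34 of 49 (median -0.73) and DNA damage response genes for 21 of 29 (median -0.70). Proteasome subunits were lower for 31 of 32 (median -0.69) and ribosomal proteins for 55 of 81, with 2 higher (median -0.36). Histone genes went both ways, with 24 of 60 lower, among them his-67 (-1.91 ± 0.25), and 11 higher (median -0.35; fry adjusted p = 0.256). Camera adjusted p-values for these 7 lists were 1.33e-11, 1.27e-06, 2.96e-12, 6.60e-08, 1.39e-13, 1.48e-12 and 0.000346 in that order, and 0.731 for each with an estimated correlation. Y49E10.16 was lowest, at 2.32 ± 0.304 TPM against 34.5 ± 5.78 TPM in N2 (SD, n = 3 each). The htp-3 replicate 2 library stood nearer to N2. Its mean change of the germline list from the N2 mean was -0.13, against -1.14 and -0.78 in the other htp-3 libraries and -0.12 in the lowest N2 library. For the oocyte list it was -0.41 against -1.37 and -1.002, and for major sperm proteins 0.50 against 1.70 and 2.12, where the N2 libraries were at -0.94, -0.13 and 1.07. Without it the list medians were -1.38 for oocyte, -1.06 for germline and 2.01 for major sperm proteins, all still called by camera, 5525 genes were higher and 3297 lower, and the collagen list gained a call (median 0.54, camera adjusted p = 0.0125).

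The other lists were not called by camera in htp-3. DAF-16 targets were higher for 12 of 20 and lower for 1 (median 0.59), oxidative stress genes for 13 of 27 and 4 (median 0.50), heat shock genes for 7 of 22 and 5 (median 0.76), early embryo markers for 13 of 20 and 3 (median 0.53), gonad sheath markers for 6 of 13 and 1 (median 0.38) and male soma markers for 2 of 4 and 0 (median 0.27). Medians changed sign under median-of-ratios scaling for vitellogenins (0.24 to -0.18; 3 of 6 higher, 1 lower), the mitochondrial response (0.07 to -0.33; 4 of 15 higher), the endoplasmic reticulum response (0.07 to -0.11; 6 of 21 higher, 4 lower), the respiratory chain (0.09 to -0.33; 7 of 36 higher, 3 lower) and hypodermis markers (0.17 to -0.00; 4 of 12 higher, 3 lower). Under the same scaling the higher and lower counts in htp-3 were 14 and 7 for lipid metabolism, 7 and 2 for DAF-16 targets, 9 and 12 for oxidative stress genes, 3 and 9 for heat shock genes, 3 and 9 for the endoplasmic reticulum response and 2 and 4 for the mitochondrial response. They were 5 and 11 for the respiratory chain, 7 and 29 for histones, 97 and 33 for F-box genes, 42 and 13 for collagens, 5 and 3 for gonad sheath markers and 871 and 215 for X chromosome genes. Adjusted over the list alone, the higher counts in htp-3 were 13 for other sperm genes, 24 for major sperm proteins, 11 for heat shock genes, 73 for xenobiotic metabolism, 13 for DAF-16 targets, 50 for collagens, 21 for muscle and 1192 for X chromosome genes. The lower counts were 38 for meiotic genes, 22 for the DNA damage response, 56 for ribosomal proteins and 78 for X chromosome genes, and no other count changed.

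Genes common to the mutants were counted next, since the series names all 3 as one question. In all 3 mutants 20 genes were higher and 2 lower than in N2, where independent lists would give 5.71 and 0.434, and lists independent of dsb-2 alone, given the overlap of spo-11 and htp-3, 9.63 and 1.58. These values leave out the shared N2 libraries, so the excess is not taken as a shared effect. Of the 20 genes 17 lay on chromosome V, and they were 14 with parallel genes counted once. The 2 lower genes were dsb-2 and C46G7.5. The higher ones included clec-209, F56A4.3, F07B7.2 and irld-53 on chromosome V. The count of lower genes was 0 without N2 replicate 2, without N2 replicate 3 or without spo-11 replicate 1, and 1 without dsb-2 replicate 1, dsb-2 replicate 2, dsb-2 replicate 3, spo-11 replicate 2, spo-11 replicate 3 or htp-3 replicate 3.

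In both spo-11 and htp-3, 5057 genes were higher and 2150 lower, where independent lists would give 2999 and 592. Under median-of-ratios scaling 4512 were lower in both. Overlap of calls from the shared N2 libraries was not measured, since simulated unchanged mutants hold no effects to call (0 shared in each of 100 simulations). The fold changes of the pair correlated with r = 0.73 across genes (simulated 0.50) and had a covariance of 0.877 (simulated 0.0264). Genes are not independent replicates, and part of the overlap may come from the shared N2 libraries, which are too few to split. The dsb-2 fold changes had r = -0.01 with spo-11 and 0.04 with htp-3 (simulated 0.50 each), with covariances of -0.0039 and 0.01 (simulated 0.0263 and 0.0264). The simulated mutants had no effects, so their r of 0.50 comes from the shared N2 libraries alone. It is not the r to expect by chance where spo-11 and htp-3 have many changed genes. No pair is therefore called more or less alike than chance from its r.

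The mutants were then compared directly. The htp-3 and spo-11 strains differed at 1106 genes higher and 5264 lower in htp-3. The sperm gene msp-40 (-7.82 ± 0.48), the collagen gene col-146 (-5.78 ± 0.54) and the immune genes ilys-3 (-5.96 ± 0.28) and irg-5 (-5.52 ± 0.28) were lower in htp-3 (log2 fold changes, SE). Higher in htp-3 were dpy-20 (4.83 ± 0.16) and the aspartyl protease gene asp-10 (3.65 ± 0.32). For dpy-20 an effect of the mutation was not told apart from another feature of the strain. The share of higher calls was 17.4%, against 45.9% under median-of-ratios scaling and 35.3% under upper-quartile scaling, with 3062 and 2258 higher genes.

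The spo-11 strain had 7635 genes higher and 3243 lower than dsb-2, with col-146 (7.21 ± 0.54) and nspd-1 (6.87 ± 0.59) highest and Y102A5C.36 (-4.64 ± 0.27) lowest. The htp-3 strain had 5673 higher and 3146 lower than dsb-2, with dod-21 (5.77 ± 0.26) highest and his-66 (-3.42 ± 0.63) lowest. Higher shares of 70.2% and 64.3% became 52.2% and 47.6% under median-of-ratios scaling, where 5558 and 4806 genes were lower.

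The chromosomal distribution of calls was tested because strains can differ near a mutated gene. In spo-11, X chromosome genes were called higher in 80.7% of cases against 51.6% elsewhere (Fisher's exact odds ratio 3.91, adjusted p = 1.73e-129), and in htp-3 in 63.1% against 35.8% (odds ratio 3.06, adjusted p = 6.26e-107). Higher calls were less frequent on chromosomes I and III in both, at 42.4% and 40.8% in spo-11 (adjusted p = 1.36e-42 and 3.12e-50) and 26.6% and 28.2% in htp-3 (adjusted p = 6.11e-44 and 3.81e-32). They were also less frequent on chromosome II, at 52.4% in spo-11 and 34.9% in htp-3. On chromosome V they were more frequent in both, at 63.9% against 53.6% elsewhere in spo-11 (adjusted p = 2.61e-21). In htp-3 these shares were 49.3% against 37.2% (adjusted p = 9.77e-29). In dsb-2, 22 of 2618 chromosome V genes and 4 of 11032 others were higher (odds ratio 23.4, adjusted p = 2.49e-12), and 6 of 2356 chromosome II genes and 4 of 11294 others were lower (odds ratio 7.21, adjusted p = 0.00479). Genes are not independent of each other in these tests. Of 36 tests 25 passed. Without genes within 5 Mb of the mutated gene 25 passed as well, but the excess of lower genes on chromosome II in dsb-2 was lost (2 of 1517 against 4 of 11294, adjusted p = 0.203) and one on chromosome IV in htp-3 was gained (adjusted p = 0.0214).

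**Figure D4:**
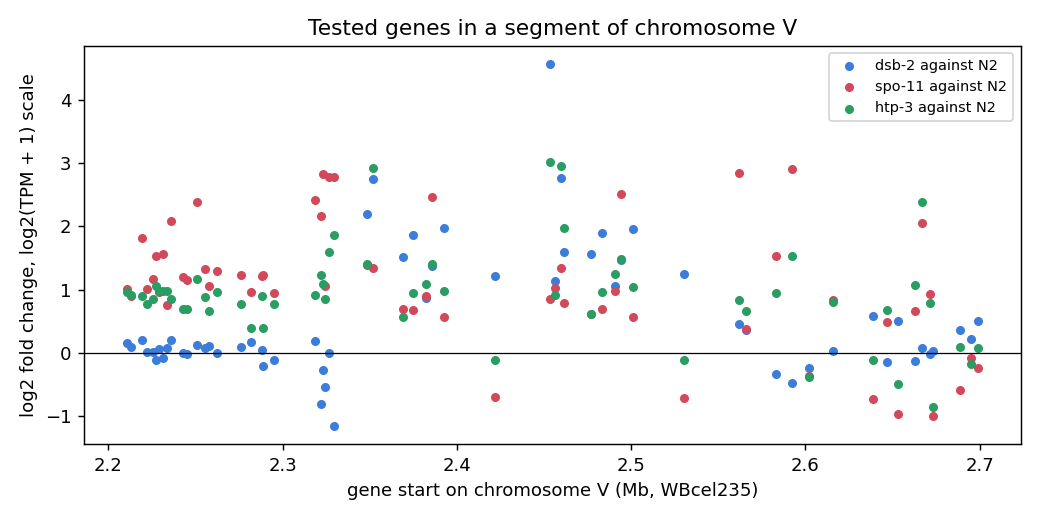
Log2 fold changes against N2 on the log2(TPM + 1) scale of tested genes between 2.2 and 2.7 Mb of chromosome V (WBcel235), one point per gene and mutant. In dsb-2 the called genes lie between 2348215 and 2531174.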

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

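The tests in this part were chosen only after the result was seen, other than the test of a duplication on chromosome V and the comparisons between mutants.

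The difference between mutants was tested directly by limma. The change from N2 was higher in spo-11 than in dsb-2 for 7635 genes and lower for 3243. It was higher in htp-3 than in dsb-2 for 5673 genes and lower for 3146, and higher in htp-3 than in spo-11 for 1106 and lower for 5264. Of genes called in opposite directions against N2, 3 were higher in spo-11 and lower in dsb-2, and 4 the reverse. Between htp-3 and dsb-2, 1 was higher in htp-3 and 0 the reverse, and between htp-3 and spo-11 there were 29 each way. With the libraries of a comparison fitted alone, each real grouping was 1 of 10 splits, too few for a share under 0.05. The real groupings gave 18 genes for dsb-2, 11132 for spo-11 and 7651 for htp-3 against N2, and 11096 for spo-11 against dsb-2, 8196 for htp-3 against dsb-2 and 5878 for htp-3 against spo-11. The highest other split gave 0 in each. For htp-3 against spo-11, whose numbers were taken as pairs, 4 splits part every pair; with the replicate number as a block the real one gave 6702 genes and the highest other of these 0.

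Genes higher in dsb-2 lay in clusters on chromosome V. Reads shared by the parallel genes found do not alone account for this: with these counted once, 15 of 19 groups were on V (Fisher's exact p = 2.89e-08). That p-value takes neighbouring groups as independent, which groups of 1 cluster may not be. Genes of low value, such as irld-53 (0.262 TPM in N2), may also have escaped the search for parallel genes. A single copy number change common to the cluster is argued against by a gap of 1.55 on the log2 scale between F56A4.2 (2.77 ± 0.30) and C13B7.6 (1.22 ± 0.16). A duplication with unequal effects may still be present: the median of 1.01 of cluster genes not called met the value set in advance (at least 0.4), but only 2 such genes exist, and 10 were asked for only after it was seen. A difference carried by the N2 stock cannot be told apart from an effect of dsb-2: 19 of the 22 genes were higher in htp-3 (Fisher's exact p = 8.16e-06) and 17 in spo-11, but the same N2 libraries serve each comparison, the medians were 1.83 in dsb-2, 1.18 in htp-3 and 0.75 in spo-11, and 15 genes differed between htp-3 and dsb-2 and 19 between spo-11 and dsb-2, where 64.6% and 79.7% of all genes tested differed.

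The him-5 transcript was near 0 in the libraries labelled spo-11. A lower share of germline RNA is argued against by a gap of 2.05 on the log2 scale between him-5 and rme-2, the lowest of the other 100 germline list members. A deletion reaching the neighbours is argued against by the 13 tested genes within 20 kb, whose median log2 fold change was 1.82. A further lesion in the strain or a wrong label cannot be told apart from an effect of spo-11, since the deposited values hold no sequence of the alleles. Under either, him-5 would be low in every library, and it was under 10% of the N2 mean in all 3. This cannot decide, because him-5 was picked for its low values there and an effect of spo-11 would give the same. Unrelated genes would also be at 0 there alone. F31E9.6, lsy-27 and fbxb-7 were at 0 in every spo-11 library and at 1 TPM or more in every other library. All lie between 17313602 and 17379226 on chromosome V, which also holds him-5. Being close together, they cannot be counted as separate signs or as genes unrelated to each other.

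Neuron, muscle, immune and major sperm protein lists were called higher and the oocyte list lower in spo-11 and htp-3 by camera, though none with an estimated correlation (adjusted p of 0.731, and for major sperm proteins 0.863 and 0.903), and hypodermis and gonad sheath lists were called in neither. Less oocyte and germline RNA alone would raise markers of every other tissue alike. The scores did not all rise alike: the smallest neuron rise exceeded the largest gonad sheath rise by 0.686 in spo-11. In htp-3 it exceeded the largest hypodermis rise by 0.743. These gaps cannot decide against that cause, because gonad sheath and hypodermis were picked as the somatic lists seen to rise least. Whether the markers compared are also made in the germline was not tested. The gaps were 1.05 and 0.771 over members of at least 1 TPM in N2, but muscle, though below neurons in each of the 6 libraries, was not apart by more than their spread (gaps -0.12 and -0.0899, or 0.178 and 0.0277 at 1 TPM), the gap to intestine was 0.633 in spo-11 but 0.0632 in htp-3, and a share of germline RNA acting with other changes was not tested. More reads in spo-11 are argued against, since its deepest library held fewer reads than the shallowest N2 library (difference -2.13 M reads). Younger mutant animals may contribute and cannot be told apart from the mutations without a library of known stage. They would have sperm and collagen genes higher and vitellogenins lower. Vitellogenins had 4 lower calls (3 in spo-11, 1 in htp-3) and 4 higher (1 in spo-11, 3 in htp-3). Under median-of-ratios scaling 4 were lower and 0 higher in spo-11, and 1 and 2 in htp-3. In spo-11 27 of 28 major sperm proteins, 32 of 34 other sperm genes and 109 of 126 collagens were higher. The lower ones numbered 0, 0 and 1. The same lists in htp-3 had 23, 14 and 51 higher and 1, 2 and 8 lower.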

How the results depend on the processing

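RPKM in place of TPM and limma-voom on rebuilt reads were chosen after seeing the data. The test planned for counts, edgeR's quasi-likelihood test, was not run, and neither was DESeq2. The rebuilt reads were tested with limma-voom alone. The dsb-2 and htp-3 transcripts stayed lower in their own mutants under median-of-ratios scaling, the block, RPKM, limma-voom and each library left out. Numbers of genes or lists called per comparison or shared, where not named here, stayed within 1.5 times, which does not cover members called within a list; where no cause is given, the cause was not tested. With median-of-ratios scaling, lower genes numbered 5449 (spo-11) and 4743 (htp-3) against N2, 5558 and 4806 against dsb-2, 4512 shared by spo-11 and htp-3 and 4 shared by all 3 mutants; higher genes in htp-3 against spo-11 numbered 3062; and the spo-11 transcript reversed in spo-11 (-0.65). With upper-quartile scaling the last count was 2258 and 4 lower genes were shared by all 3. With a minimum of 5 TPM, where fewer genes are tested, 4731 were higher in spo-11 than in N2, 4757 higher than in dsb-2, and 3042 lower in htp-3 than in spo-11. With a fold change of at least 2, a stricter rule, lower genes numbered 881 (spo-11) and 277 (htp-3) against N2, 1165 and 767 against dsb-2, and 2972 in htp-3 against spo-11; higher genes in htp-3 numbered 2844, 2928 and 309 against N2, dsb-2 and spo-11; 2522 were higher and 186 lower in both spo-11 and htp-3, and 9 higher and 1 lower in all 3. For dsb-2 with only the 2 groups compared, 15 were higher and 3 lower, and 12 higher and 1 lower in all 3; lower genes in dsb-2 numbered 4 with no filter, 5 with a pseudocount of 5 and 19 with RPKM. Genes lower in all 3 numbered 1 with no filter, 1 with a pseudocount of 0.1, 5 with RPKM and 4 with limma-voom, and 12 were higher in all 3 with a pseudocount of 5. With an estimated correlation 0 lists were called in dsb-2, 0 in spo-11 and 0 in htp-3, and fry called 0, 25 and 22. Same-numbered libraries correlated above 0.1 in 11 of 18 pairs (-0.39 to 0.44), and 9 of 12 libraries correlated best with their own number. With the replicate number as a block, lower genes in dsb-2 numbered 17, and no other count moved by over 1.5 times: 1189 higher and 5391 lower in htp-3 against spo-11, 7658 and 3173 in spo-11 and 5533 and 2931 in htp-3 against N2. Leaving out each library gave 2 to 14 lower genes in dsb-2, 1789 to 3297 in htp-3 and 0 to 2 in all 3, and -0.027 to 0.41 for the spo-11 transcript. The list medians in dsb-2 ranged from -0.80 to 0.22 for major sperm proteins and from -0.069 to 0.43 for histones. The value of 0.22 came without N2 replicate 3 and -0.069 without dsb-2 replicate 1. Camera, which called neither list with all libraries, then called both in either direction. Major sperm proteins were called lower without N2 replicate 1 (adjusted p = 2.14e-06) and higher without N2 replicate 3 (0.0321). Histones were called lower without dsb-2 replicate 1 (0.012) and higher without dsb-2 replicate 2 (8.21e-08). With the block major sperm proteins were called lower (0.0384). Depth of at least 32422219 mapped reads limits genes of low value most.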

Other observations

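The genes below were chosen after their values were seen. Those named first were called in opposite directions in spo-11 and htp-3 against N2 (limma on log2(TPM + 1)), and no group of genes was tested among such calls. The log2 fold changes of sqt-1 were 1.25 in spo-11 and -1.34 in htp-3, those of rol-6 were 1.35 and -1.04, those of rol-8 were 1.20 and -0.85, and those of sqt-2 were 1.09 and -1.07. The sperm fate gene fog-1 was at 1.69 and -0.74, and the C-type lectin gene clec-53 at -2.16 and 1.16. The sperm gene msp-40 was at 5.112 and -2.71, with the reservation that reads of msp genes are hard to assign.

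The dpy-20 gene, which acts in cuticle formation, was listed at 28.6, 37.9 and 38.8 TPM in the htp-3 libraries. It was at 0.226, 0.329 and 0.222 TPM in spo-11, at 0.018, 0.103 and 0.034 TPM in N2, and at 0.050, 0 and 0.019 TPM in dsb-2. Whether this comes from the htp-3 mutation or from another feature of the strain was not tested. On chromosome V, F31E9.6 (17313602 to 17315153), lsy-27 (17348665 to 17350180) and fbxb-7 (17377406 to 17379226) were the 3 genes listed at 0 in every spo-11 library and at 1 TPM or more in every other library. Their lowest values elsewhere were 2.41, 9.51 and 3.002 TPM.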
